A study of Mus musculus with 4 samples.

How the data were processed

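RNA from colonies was hybridised to Affymetrix mouse expression arrays with a single colour, 2 arrays for control and 2 for Wnt3A. The deposited table held log2 values made with RMA, per the submitters' processing notes, which give no version. The centring step is not given in the sources used here: the median of every one of the 45101 rows over the 4 samples was 0 in the deposited log2 values, so each value is a difference from that median and levels were removed. Differences between samples are unaffected by this centring. Column medians were 0.014 in control 1, -0.016 in control 2, 0.02 in Wnt3A 1 and -0.016 in Wnt3A 2. The log2 base was checked from the spacing of the stored numbers.

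Of the 45037 probe sets other than array controls, 34945 had a single gene symbol in the platform annotation, 932 had several and 9160 had none, and only the first kind was used for genes. The Entrez identifiers of 34754 of them were found in a RefSeq gene table, which changed 0 symbols. Before the data were examined it was fixed that the brightest probe set would stand for a gene, that the lowest 40% of genes by mean would be left out, with 60% as an alternative, and that an intensity trend would be tried. Centred values allow none of these. In their place a median level band was read from the precision with which the deposited numbers were stored, as log2 8 to 16 (45.3% of probe sets), 4 to 8 (41.9%) or below 4 (12.8%), a choice made after seeing that values were centred. On simulated values the bands were called correctly for 100.0%, 73.6% and 73.0% of probe sets, and the errors placed probe sets too high. A gene was the mean of its probe sets in its highest band, and 1271 of 18193 genes below log2 4 were left out. This left 16922 genes.

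Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), with no covariate, 2 residual degrees of freedom and 2.56 prior degrees of freedom. Standard errors are those of this moderated fit. An exact permutation test of 2 against 2 samples cannot give a two-sided p below 0.33. On simulated data with 200 changed genes among 16922, the fit recovered 0% of changes of 1 log2 unit, 78% of changes of 2 and 93.7% of changes of 3 at an adjusted p under 0.05 for the control against Wnt3A comparison. The simulated genes were independent, with variances drawn from the fit's own prior and no difference shared by arrays of the same number. These shares may therefore not hold for the real arrays.

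Gene groups were 35 lists fixed before the data were examined, tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists, with an estimated correlation and fry beside it. With 2 arrays a group, the estimated correlation rests on 2 residual degrees of freedom. That form of camera also refers its statistic to these 2 degrees of freedom, where the preset form uses nearly the number of genes. Few lists could pass it after adjustment, so failing it does not tell a lack of power from a lack of difference. The text names the 10 genes with the largest positive and the 10 with the largest negative differences among those past the adjusted threshold with separated groups, with places left going to genes with an unadjusted p under 0.05 and the same separation. It also names some, not all, of the members that were among the 4 with the largest absolute difference in a list, and always Procr, Axin2, Lef1 and the sort marker genes. Genes past the threshold over their own list alone were named in addition. That adjustment was made within each list with no correction across lists. It passed 25 members, repeats included, in 13 lists and none in 22. Whether a gene passes it depends on the list that holds the gene. Probe sets of a named gene that differed by more than 1 log2 unit were looked up, which applied to 17 genes, among them Nrp1, Pdgfra, Ror1, Tnfrsf19, Tspan8 and Aen.

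Alternatives were no filter on low values, the upper level band alone, the mean of all probe sets, quantile normalization, centring of each sample, robust eBayes, the replicate number as a block, each array left out, all probe sets tested, other thresholds, and other set tests. Where an array is left out, the lone sample of its group is assumed to vary like the other group. The replicate numbers are then also unbalanced between the groups, so a swing may reflect the difference between numbers and not only an unsteady Wnt3A difference. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.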

Results

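Gene expression was measured in mouse mammary basal epithelial cells grown as colonies in Matrigel, a basement membrane gel, with or without purified Wnt3A, a secreted protein that activates the canonical Wnt pathway. The cells came from virgin CD1 females 8 to 12 weeks old and were sorted as lineage-negative, CD24-positive, CD29-high, a gate enriched for mammary stem cells. Colonies were grown with 50 ng/ml EGF and either 200 ng/ml Wnt3A or its vehicle, and RNA was taken from colonies of passage 2 after 6 to 7 days. Each group had 2 arrays, named control 1, control 2, Wnt3A 1 and Wnt3A 2. The labels do not say whether the 2 arrays of a group came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. Deposited values were log2 differences from each probe set's median over the 4 samples and carry no absolute level. The number of arrays limits the precision, and the median standard error of a gene's difference was 0.16 log2 units.

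The comparison asked which genes differ between colonies grown with Wnt3A and with vehicle. Procr, which encodes the endothelial protein C receptor, was 2.75 ± 0.69 log2 units (SE) higher with Wnt3A, a 6.74-fold difference, with values of -1.87 and -0.66 in the control arrays and 0.66 and 2.31 in the Wnt3A arrays, and it differed by 1.93 without Wnt3A 2 and 3.58 without Wnt3A 1. Axin2, a feedback inhibitor and standard target of canonical Wnt signalling, was 1.76 ± 0.31 log2 units higher, with -0.58 and -1.18 in the controls and 1.20 and 0.58 with Wnt3A. Epidermal keratinocyte genes were among the largest positive differences, and the oxytocin receptor gene Oxtr (-2.60 ± 0.13) and the glycogen phosphorylase gene Pygl (-2.95 ± 0.18) were among the largest negative ones. No single gene passed the test: limma called 0 of 16922 genes at an adjusted p under 0.05, the smallest adjusted p was 0.22, and 1300 genes had an unadjusted p under 0.05 against 846 expected by chance, 628 higher and 672 lower with Wnt3A. Values of single genes are therefore given as measured differences.

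The 10 largest positive differences among genes whose arrays separated by group and whose unadjusted p was under 0.05 were those of Krt1 (4.72 ± 1.78), Stfa3 (4.11 ± 0.39), Csta1 (3.79 ± 0.42), Krt73 (3.52 ± 0.57), Tslp (3.27 ± 0.56), Sprr1b (2.99 ± 0.72), Defb1 (2.78 ± 0.35), Procr, Teddm3 (2.64 ± 0.99) and Elovl4 (2.47 ± 0.58). Krt1 and Sprr1b encode a keratin and a cornified envelope protein of differentiating keratinocytes, Tslp a cytokine made by epithelia, Defb1 an antimicrobial peptide and Elovl4 an enzyme that makes very long chain fatty acids. The Krt1 value was set largely by Wnt3A 2, at 6.28 against 0.94 in Wnt3A 1, and without Wnt3A 2 the difference was 2.05 for Krt1 and 1.18 for Teddm3, against 7.39 and 4.09 without Wnt3A 1. Stfa3 and Csta1 belong to the stefin family of near-identical protease inhibitor genes, whose probes may share signal, so neither value can be assigned to a single family member with certainty. The 10 largest negative differences under the same limits were those of Pygl, Krt15 (-2.62 ± 0.34), Oxtr, Selenbp1 (-2.46 ± 0.49), Kazald1 (-2.45 ± 0.26), Foxa1 (-2.34 ± 0.49), Fabp7 (-2.34 ± 0.51), Frem2 (-2.33 ± 0.40), Cdo1 (-2.33 ± 0.53) and Apoe (-2.14 ± 0.62). Krt15 is a basal keratin, Foxa1 a transcription factor of hormone-sensing luminal cells, and Apoe a lipid carrier. Both Wnt3A arrays lay on the same side of both controls for 35.4% of genes, where chance gives 33.3%. Of these, 318 differed by at least 1 log2 unit, 182 higher and 136 lower. The second probe set of Oxtr, in a lower level band, differed by -0.17, and the mean of both gave -1.39. Without Wnt3A 1 the Apoe difference was -1.25, and without control 2 that of Cdo1 was -1.55.

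**Figure D1:**
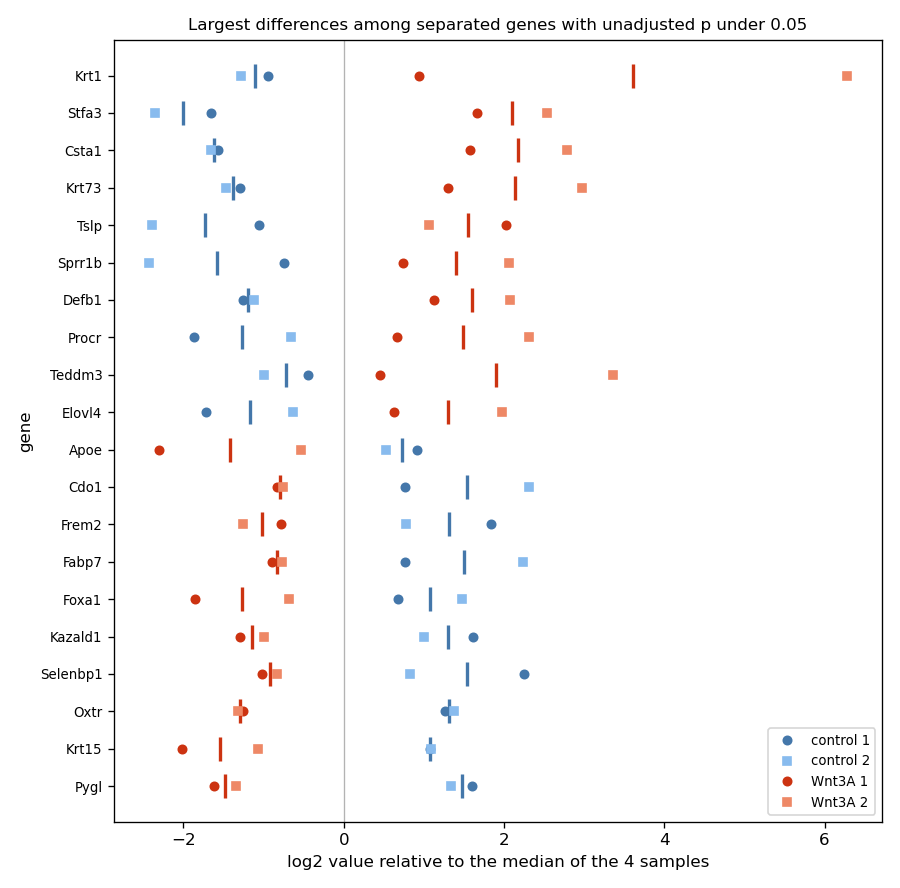
Log2 value relative to the median of the 4 samples (x axis) for the 10 largest positive and 10 largest negative differences among separated genes with an unadjusted p under 0.05 (y axis). Points are single arrays and vertical ticks are group means of 2 arrays, and Krt1 in Wnt3A 2 lies farthest out, at 6.28.

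Textbook Wnt target and feedback genes were tested as a group because Wnt3A was the treatment. The 27 measured members had a median difference of 0.08 log2 units, and camera did not separate them from the other genes (p = 0.069, adjusted p = 0.14, and adjusted p = 0.73 with an estimated correlation). Fry's mixed test, which asks whether members change in either direction, called the list (adjusted p = 0.0017). Of these, 12 were higher and 6 lower in both Wnt3A arrays than in both controls. Besides Axin2, the positive differences included Tnfrsf19 (1.54 ± 0.82), Notum (1.21 ± 0.27), which encodes a secreted Wnt deacylase, and Lgr6 (1.19 ± 0.30). Lgr5, also on this list, was among the members separated lower (-0.81 ± 0.15). When adjusted over the list alone, 0 members passed. The Tnfrsf19 value rested on Wnt3A 2, at 2.61 against 0.15 in Wnt3A 1: it was 0.31 without Wnt3A 2 and 2.77 without Wnt3A 1, its other probe sets differed by -0.02 and 0.15, and the mean of all its probe sets gave 0.56. Lef1, a transcription factor of the pathway, differed by 0.25 ± 0.19, by 0.03 without Wnt3A 1, by 0.47 without Wnt3A 2 and by 0.06 as the mean of all its probe sets. The unadjusted camera result of the list passed the threshold when control 2 was left out (median 0.13) and when Wnt3A 2 was left out (0.16), and its median was 0.03 without Wnt3A 1. The second Axin2 probe set, in the lowest level band, differed by -0.12, and the mean of both probe sets gave 0.82.

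The Wnt ligand list, which as fixed also holds R-spondin genes, was called higher by camera (20 measured members, median 0.10, adjusted p = 0.046). With an estimated correlation the adjusted p was 0.73. In the list, 7 members were separated higher and 0 lower. Wnt10a differed by 0.79 ± 0.21. This median was 0.16 without control 1, 0.03 without control 2, 0.02 without Wnt3A 1 and 0.28 without Wnt3A 2, and the call ended without control 1, without Wnt3A 1, with no filter on low values, with the upper level band alone and after quantile normalization. The 19 Wnt receptors and co-receptors had a median of -0.12 (camera adjusted p = 0.45), and 4 were separated higher and 7 lower, the latter including Ror1 (-1.26 ± 0.14) and Lgr5 (-0.81 ± 0.15), both past 0.05 when adjusted over the list alone against 0 over all genes. The receptor median was 0.01 without Wnt3A 2. The 2 Lgr5 probe sets differed by -0.14 and -1.48, and the mean of all Ror1 probe sets gave -0.53. Secreted and membrane Wnt inhibitors had a median of 0.12 (camera adjusted p = 0.15), between 0.06 (without Wnt3A 1) and 0.41 over the alternatives, and Sfrp1 (-1.05 ± 0.15) was the member that passed when adjusted over the list alone.

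Squamous differentiation genes, which keratinocytes switch on as they cornify, showed the largest group difference. Their median was 1.25 log2 units higher with Wnt3A over 29 measured members, 26 had a higher mean, and 19 were separated higher against 0 lower. Camera called the list higher (adjusted p = 1.5e-11; adjusted p = 0.73 with an estimated correlation). Besides Krt1 and Sprr1b, the examples were Krt10 (3.14 ± 1.20), a keratin of suprabasal cells, and Sprr2h (2.38 ± 1.05), which were 1.36 and 0.81 without Wnt3A 2 and 4.93 and 3.96 without Wnt3A 1. Adjusted over the list alone, 3 members passed against 0 over all genes: Krt16 (1.68 ± 0.19), Krt6a (0.72 ± 0.14) and S100a9 (2.08 ± 0.40), the first 2 being keratins of activated epidermis, and these 3 were picked out after their values were seen. The list median was -0.47 and -0.29 in the control arrays, 0.19 in Wnt3A 1 and 1.14 in Wnt3A 2, and it was 0.60 higher when Wnt3A 2 was left out and 1.66 higher when Wnt3A 1 was left out.

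Hedgehog and Hippo-YAP response genes were called higher (23 members, median 0.19, camera adjusted p = 2.2e-04; adjusted p = 0.73 with an estimated correlation), with 11 separated higher and 0 lower. Shh, the ligand Sonic hedgehog, differed by 2.46 ± 0.26 and Gli2, a transcription factor of that pathway, by 1.86 ± 0.15, and both passed when adjusted over the list alone. The second Shh probe set, in the lowest level band, differed by 0.23, and the mean of both gave 1.35. The YAP targets Ccn2 (1.78 ± 1.10) and Ankrd1 (1.83 ± 0.74) were lowest in control 1, at -3.37 and -2.07, and differed by 0.13 and 0.88 without that array and 3.43 and 2.78 without control 2. The list median was 0.12 without Wnt3A 1, and it kept its call when each array was left out in turn.

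TGF-beta and BMP pathway genes were called higher (28 members, median 0.14, camera adjusted p = 0.033; adjusted p = 0.73 with an estimated correlation), with 10 separated higher and 5 lower. Bmp2, a BMP ligand, differed by 1.30 ± 0.13 and passed when adjusted over the list alone. The median was 0.12 without control 1, 0.23 without control 2, 0.06 without Wnt3A 1 and 0.26 without Wnt3A 2, and the call ended without control 1, without Wnt3A 1, with the upper level band alone and with the replicate number as a block (camera adjusted p = 0.06). EGF receptor ligands and MAPK response genes were not called by camera (28 members, median 0.08, adjusted p = 0.37, and 0.01 without control 1), with 6 separated higher and 5 lower. The ligand genes Epgn (1.65 ± 0.21) and Ereg (1.06 ± 0.21) still passed when adjusted over the list alone, as did Fosl1 (0.77 ± 0.15), which was picked out after its value was seen. Notch pathway genes (median 0.03, adjusted p = 0.68) and FGF and insulin-like growth factor genes (-0.02, adjusted p = 0.58) were not called, with medians between -0.15 and 0.10 over the alternatives.

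Inflammatory and NF-kappaB genes were called higher (30 members, median 0.25, camera adjusted p = 0.0086; adjusted p = 0.73 with an estimated correlation), with 9 separated higher and 1 lower. Ptgs2, the inducible cyclooxygenase, differed by 2.00 ± 0.42 and the cytokine gene Il1a by 1.99 ± 0.27, the latter past 0.05 when adjusted over the list alone. The median was 0.39 without control 1, 0.46 without Wnt3A 2 and 0.17 without Wnt3A 1, where the call ended. Interferon response genes were called lower (28 members, median -0.38, camera adjusted p = 0.0086; adjusted p = 0.80 with an estimated correlation), with 0 separated higher and 5 lower, and the chemokine gene Cxcl10 differed by -1.97 ± 0.36. Their median was 0.63 in control 2 and -0.21 in control 1, against -0.55 and 0.12 in Wnt3A 1 and Wnt3A 2. Within each replicate number it was thus lower with Wnt3A. With the number as a block the list was still called (camera adjusted p = 6.5e-06 at the preset correlation), though pairing is not established. The difference was 0.03 without control 2 and -0.09 without Wnt3A 1, where the call ended, and -0.91 without control 1 and -0.84 without Wnt3A 2.

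Collagen and matrix genes were called higher (36 members, median 0.30, camera adjusted p = 6.1e-04; adjusted p = 0.73 with an estimated correlation), with 14 separated higher and 1 lower. Fibronectin, Fn1, differed by 1.88 ± 1.04, tenascin C, Tnc, by 1.50 ± 0.71 and biglycan, Bgn, by -2.07 ± 0.83. Matrix proteases and inhibitors were also called higher (22 members, median 0.22, adjusted p = 0.007; adjusted p = 0.73 with an estimated correlation), with 10 separated higher and 2 lower, among them the urokinase gene Plau (1.81 ± 0.99), its receptor gene Plaur (1.58 ± 0.28) and Adam12 (1.70 ± 0.86). Control 1 stood apart for several of these members: Fn1 was at -3.16, Plau at -2.90, Adam12 at -2.59 and Tnc at -2.27 there, and without it they differed by 0.33, 0.36, 0.44 and 0.46, against 3.42, 3.25, 2.96 and 2.55 without control 2. Bgn differed by -1.03 without Wnt3A 2 and -3.11 without Wnt3A 1. The matrix median was 0.16 without Wnt3A 1, where the call ended, and 0.56 without Wnt3A 2. The protease median was 0.25 without control 1 and 0.28 without Wnt3A 1, where the call ended, 0.36 without control 2 and 0.45 without Wnt3A 2. Coagulation and protein C pathway genes, which hold Procr, had a median of 0.11 (camera adjusted p = 0.16), and epithelial-mesenchymal transition genes one of 0.01 (adjusted p = 0.45). Without control 2 both lists were called, with medians of 0.09 and 0.07. The coagulation median was -0.00 without control 1, 0.02 without Wnt3A 1 and 0.04 without Wnt3A 2, and that of the transition genes lay between -0.00 and 0.13 over the alternatives.

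Basal epithelial markers were called higher (22 members, median 0.29, camera adjusted p = 0.026; adjusted p = 0.73 with an estimated correlation), with 7 separated higher and 2 lower. Sfn (1.20 ± 0.20), which encodes 14-3-3 sigma, and Krt15 passed in opposite directions when adjusted over the list alone, and the call ended without control 1 (0.23) and without Wnt3A 2 (0.23). Epithelial junction genes were called higher (26 members, median 0.25, adjusted p = 0.045; adjusted p = 0.73 with an estimated correlation), with 12 separated higher and 5 lower. Grhl3 (1.31 ± 0.15), a transcription factor of the epidermal barrier, and the claudin gene Cldn8 (-1.44 ± 0.16) passed when adjusted over the list alone. The junction median was 0.12 without control 1 and 0.23 without Wnt3A 1, where the call ended, and 0.37 without control 2, and the call also ended with no filter, the upper level band alone, the mean of all probe sets and quantile normalization. Luminal epithelial markers were not called by camera (27 members, median -0.07, adjusted p = 0.45), with 7 separated higher and 8 lower, including Foxa1, Tspan8 (-2.10 ± 0.42) and Cited1 (-2.52 ± 1.16). Cited1 was at 0.09 in control 1 and 3.21 in control 2, and differed by -0.97 without control 2 and -4.08 without control 1. The luminal list was called without control 1 (-0.06), and its median was -0.31 without Wnt3A 1 and 0.20 without Wnt3A 2. The 21 proposed mammary stem and progenitor cell genes had a median of 0.01 (camera adjusted p = 0.58), between -0.07 and 0.10 over the alternatives, and the members furthest apart were Procr, Nrp1 (2.04 ± 0.58, and 1.19 without control 1), Axin2 and Tspan8. Adjusted over the list alone, Axin2, Lgr5 and Tspan8 passed there. The Nrp1 probe sets differed by 0.24 to 2.25 and those of Tspan8 by -0.33 to -2.41. The mean of all probe sets gave 1.43 for Nrp1 and -1.54 for Tspan8. Myoepithelial contractile genes had a median of 0.12 (camera adjusted p = 0.85), and Oxtr passed when adjusted over the list alone. The contractile median was -0.16 without control 1 and 0.52 without control 2, and the list was called in both cases; it was 0.49 without Wnt3A 1. Milk and alveolar genes had a median of -0.18 (adjusted p = 0.44), which was -0.50 without control 2 and -0.37 without Wnt3A 1, both called, -0.01 without control 1 and 0.08 without Wnt3A 2.

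Cholesterol and fatty acid synthesis genes were called higher (24 members, median 0.25, camera adjusted p = 6.1e-04; adjusted p = 0.73 with an estimated correlation), with 10 separated higher and 1 lower. Fasn, the fatty acid synthase, differed by 0.61 ± 0.17. Ribosome biogenesis genes were called higher (23 members, median 0.25, adjusted p = 7.7e-04; adjusted p = 0.73 with an estimated correlation), with 10 separated higher and 0 lower, among them Rrp12 (0.54 ± 0.23, and 0.30 without control 2). Without control 2 the medians of these 2 lists were 0.04 and 0.02, without Wnt3A 2 they were 0.18 and 0.20, and both calls ended in either case. Unfolded protein and amino acid stress genes were called higher (24 members, median 0.23, adjusted p = 0.0095; adjusted p = 0.73 with an estimated correlation), with 8 separated higher and 2 lower and Chac1 at 0.92 ± 0.15. Their median was 0.07 without Wnt3A 1, and the call ended without Wnt3A 2 (0.24). Genes of p53 and cell cycle arrest were called higher (20 members, median 0.15, adjusted p = 0.033; adjusted p = 0.73 with an estimated correlation), with 8 separated higher and 3 lower, and Eda2r (1.15 ± 0.21) and Aen (0.74 ± 0.13) passed when adjusted over the list alone. That call ended without control 1 (0.12), Wnt3A 1 (0.24) or Wnt3A 2 (0.17), with the upper level band alone and with the replicate number as a block (adjusted p = 0.058), and the median was 0.39 without control 2. The Aen probe sets differed by 0.01, 0.89, 0.99 and 1.08. Oxidative stress and glutathione genes had a median of 0.52 (adjusted p = 0.065), with Gsta2 at 2.22 ± 0.48. That median was 0.18 without control 1 and -0.22 without Wnt3A 2, and the list was called without control 2 (0.52), without Wnt3A 1 (0.56) and with the replicate number as a block (camera adjusted p = 0.039). Hypoxia and glycolysis genes had a median of -0.16 (adjusted p = 0.099), and adjusted over the list alone Bnip3 (-1.64 ± 0.21) and Adm (1.30 ± 0.15) passed in opposite directions, the second picked out after its value was seen. The hypoxia median was 0.03 without control 1 and -0.41 without control 2, where the list was called. Mitotic genes (-0.12, adjusted p = 0.45) and DNA replication and G1/S genes (0.01, adjusted p = 0.76) were not called with all arrays. Their medians were 0.23 and 0.31 without control 1 and, in the opposite direction, -0.46 and -0.38 without control 2. Each omission leaves the replicate numbers unbalanced between the groups, so these medians also carry the difference between numbers. With the replicate number as a block neither list was called (camera adjusted p = 0.38 and 0.89).

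No list of markers of other cell types was called. The medians were 0.03 for fibroblast markers (adjusted p = 0.97), -0.01 for endothelial markers (0.58), 0.04 for blood cell markers (0.46), 0.10 for adipocyte markers (0.34) and 0.00 for pericyte and nerve sheath markers (0.76), and over the alternatives they lay between -0.09 and 0.19. Among the genes of the sort markers, Cd24a differed by 0.04 ± 0.24, Itgb1, which encodes CD29, by 0.67 ± 0.26 (0.34 without control 1), and Pecam1, which encodes CD31, by -0.05 ± 0.27. Ptprc, which encodes CD45, was left out because its median level was below log2 4. In all, camera called 14 of 35 lists, 13 higher and 1 lower, and 0 held with an estimated correlation, where the lowest adjusted p was 0.73. Fry, which tests whether a list's genes move on balance in a single direction, called 0 lists (lowest adjusted p = 0.38), and its mixed test for change in either direction called 8: Hedgehog and Hippo-YAP (adjusted p = 1.0e-03), Wnt target (0.0017), contractile (0.0076), stem and progenitor (0.011), Wnt receptor (0.012), junction (0.016), Wnt inhibitor (0.029) and EGF and MAPK genes (0.029). Calls gained with an array left out were made at the preset correlation only.

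**Figure D2:**
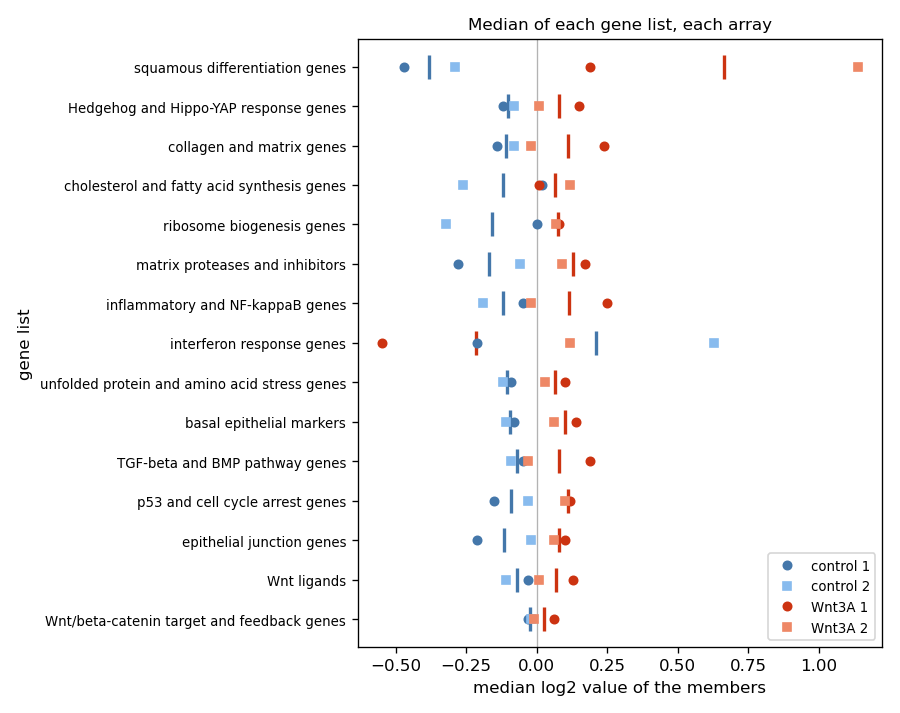
Median log2 value of the members (x axis, relative to each probe set's median over the 4 samples) for the 14 lists called by camera and the Wnt target list (y axis). Points are single arrays and vertical ticks are group means of 2 arrays, and the squamous list spans -0.47 in control 1 to 1.14 in Wnt3A 2.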

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

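All tests in this part were chosen after the results were seen. Among array controls, which no comparison used, the 18 hybridization control probe sets were 0.50 log2 units higher in the Wnt3A arrays by their median, at -0.22 and -0.31 in the controls and 0.29 and 0.17 with Wnt3A. Of 7899 probe sets with no or several gene symbols and a median level of at least log2 4, 60 were separated by group with a mean difference of at least 1 log2 unit. Of these, 48 were higher and 12 lower with Wnt3A.

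Squamous differentiation genes were 1.25 log2 units higher with Wnt3A by their median, most of all in Wnt3A 2. Wnt3A 1 was still 0.60 above the control mean, so Wnt3A 2 did not carry the whole measured difference. Of random lists of like level, 2.5% lay above 0.14, but their genes need not vary together as those of a fixed list may. The squamous list also differed by 0.66 between the replicate numbers. Whether 0.60 exceeds the spread between arrays therefore cannot be told. Genes of like brightness did not move by this much in the normalized values. The level bands had medians of -0.003 and -0.000, and 2.5% of random lists lay above 0.09 against the observed 1.25. These values thus show no shift of all such genes. Normalization holds the bands near 0 and the bands are wide, so a shift before it or of a narrower range cannot be checked. Wnt3A exposure may be the source, and 1 of the 3 splits of the samples gave a median this large, the real one, with 0.66 the highest of the others. With only 3 splits, a share under 0.05 cannot be reached, so this stays a hypothesis.

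Arrays with the same replicate number resembled each other. The difference of control 1 minus control 2 correlated across genes with that of Wnt3A 1 minus Wnt3A 2 (r = 0.45, genes not being independent replicates). Mitotic genes were lower in number 2 than in number 1 by a median of -0.50, where 2.5% of random lists of like level lay below -0.17. Genes of like brightness thus did not move by this much in the normalized values. Normalization holds the level bands near 0 and the bands are wide, so a shift before it or of a narrower range cannot be checked. The mitotic list is 1 of 7 of the 35 fixed lists that camera called between the numbers. Separate cell preparations or culture days could give such a pattern, but the labels tie no number to either, so this cannot be told apart from other causes. No biological explanation was tested.

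Control 1 lay at least 2 log2 units below the other 3 arrays for 15 genes, against 0 for control 2 and 4 for each Wnt3A array, while 23 genes in Wnt3A 2, 13 in control 2, 5 in control 1 and 0 in Wnt3A 1 lay as far above the others. Several of the 15 encode matrix or contractile proteins, among them Fstl1 (-4.75 in control 1), Tagln (-4.03), Ccn2 (-3.37), Fn1 (-3.16), Actg2 (-3.12) and Cnn1 (-2.75). Fewer fibroblasts in that sample might lower such genes, though the CD24 and CD29 gate is meant to exclude them. The 11 fibroblast markers in the upper level band, Fstl1 included, were not lower as a set. Their median in control 1 minus the mean of the others was 0.09, with an SD of 1.79. The 15 genes had -2.97, but they were picked for being low, so that value sets no size for the markers to reach. Fewer fibroblasts are thus not excluded. The other 11242 genes in the upper level band had a median of 0.04 by the same measure, with an SD of 0.38. The normalized values thus show no shift of all genes in that band in control 1. Normalization holds that median near 0 and the band is wide, so a shift before normalization or of a narrower range cannot be checked. No biological explanation beyond fewer fibroblasts was tested, since the labels name no difference between the controls.

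Of the 3 splits of the 4 samples, 1 gave as many separated genes with a mean difference of at least 1 (318, the real split, against 274 for number 1 against number 2), and 1 called as many lists (14 against 13 for the crossed split). The splits are too few for a share under 0.05. By unadjusted p under 0.05, number 1 against number 2 gave 1910 genes, the real split 1300 and the crossed split 87. The crossed split sets control 1 and Wnt3A 2 against control 2 and Wnt3A 1. It still called 13 lists at the preset correlation, so 14 called lists are near what a split that mixes the groups gave.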

How the results depend on the processing

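The upper-band filter was chosen after seeing the data, and the intensity trend and percentile filters were not run because centred values carry no level. The limma count of genes at an adjusted p under 0.05 was 0 under every alternative run, including all probe sets, a change of at least 1 and an adjusted p under 0.1. Counts by unadjusted p under 0.05 lay between 888 (upper band alone) and 2513 (all probe sets). These ends have unlike totals, 11256 genes for the first and probe sets instead of genes for the second, so they do not rank the settings. No normalization moved the median of all genes by more than 0.1. The Wnt target median stayed positive, from 0.03 to 0.16 when each array was left out, and it passed an unadjusted p of 0.05 without control 2 (0.13) and without Wnt3A 2 (0.16), for which the cause was not tested. Camera called 14 lists, between 8 (without Wnt3A 1) and 19 (without control 2) when each array was left out, with 9 without Wnt3A 2, and 10 to 14 under the filter, probe set, normalization and robust alternatives. The list count was 0 with an estimated correlation and 0 with fry. The first changes the correlation and also the degrees of freedom of the test, to 2, and the second tests a list by itself. With 2 degrees of freedom few lists could pass: the unadjusted camera p of the squamous list went from 4.2e-13 to 0.18. With the replicate number as a block, 0 genes passed, 2136 instead of 1300 had an unadjusted p under 0.05, 13 lists were called and the Wnt target median was 0.08 in the same direction. Same-numbered arrays deviated together across probe sets (r = 0.53), but the labels do not say that a number marks a shared animal or day, so pairing is not established and the fit without the block was kept. Of 801 values of the 74 named genes under alternatives, 796 kept their direction. The 5 others were Cnn1 without control 1 (-0.39), Cd24a without control 1 (-0.23) and without Wnt3A 1 (-0.12), and Pecam1 without control 1 (0.13) and without Wnt3A 2 (0.26), all with fewer samples. None of these genes was separated by group. A separated gene cannot reverse when an array is left out, and some alternatives leave the difference itself unchanged. The count of 796 was therefore largely fixed in advance and is no measure of robustness. With each array left out, Cnn1 ranged from -0.39 to 2.84, Cd24a from -0.23 to 0.31 and Pecam1 from -0.36 to 0.26. Signal over background is unknown here beyond the level bands.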

Other observations

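The tests in this part were chosen after the results were seen. Differences between the replicate numbers followed recognisable gene groups. Interferon response genes were a median of 0.71 log2 units higher in number 2 than in number 1 (camera adjusted p = 4.2e-11), in 26 of 28 members, with Oas1a, an antiviral enzyme gene, at -0.98 and 0.98 in control 1 and control 2 and -0.99 and 1.06 in Wnt3A 1 and Wnt3A 2. Xaf1 differed by 2.28 ± 0.21 in the same direction. DNA replication genes (-0.41, adjusted p = 4.2e-06) and mitotic genes (-0.50, adjusted p = 5.4e-06) were lower in number 2 in every measured member of both lists, 26 and 25. Oxidative stress genes (0.50, adjusted p = 5.4e-05), contractile genes (0.69, adjusted p = 6.7e-05) and squamous genes (0.66, adjusted p = 1.5e-04) were higher in number 2, and milk genes (-0.55, adjusted p = 2.1e-04) were lower, with the casein gene Csn1s1 at -3.26 ± 1.01. An estimated correlation was not run for these differences, and Oas1a and Xaf1 were picked out after their values were seen.

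Poly-A spike controls, added to RNA before labelling, had medians of -0.94 in control 1, 0.86 in control 2, -0.12 in Wnt3A 1 and 0.12 in Wnt3A 2. The 18S ribosomal RNA probe sets differed by -0.61 by their median with Wnt3A, with 1.09 in control 2. Differences between 3' and 5' probe sets of Gapdh and Actb lay between -0.09 and 0.07 in the 4 arrays, relative to their medians. Pdgfra, a fibroblast marker, differed by -1.76 ± 0.47 between Wnt3A and control, opposite to Fstl1 (2.61 ± 1.65, and 0.16 without control 1). The Pdgfra value rested on 1 of 3 probe sets, the others differing by 0.02 and -0.54 and the mean of all by -0.76, and it was -1.14 without control 1.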
